A study of Homo sapiens with 4 samples.

How the data were processed

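RNA sequencing libraries came from 2 human cell lines, each grown in 2 ways, with 1 library per group and 4 libraries in all. The line 293T is a transformed human embryonic kidney line, and MCF-7 is an oestrogen receptor positive breast cancer line. Monolayer cells were grown in serum (10% FBS). Sphere cultures were grown on dishes coated with 0.5% poly-HEMA, which prevents attachment, in a medium with the B27 supplement, 10 ng/mL bFGF and 20 ng/mL EGF, per the labels' protocols, which name no serum for it. By these protocols the culture formats differ in attachment, medium and added growth factors together. Total RNA was extracted with TRIzol and treated with DNase, per the labels' protocols, and whether the libraries kept strand is not given in the sources used here.

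The authors deposited 1 table per library with 42098 rows, 1 per RefSeq transcript and locus. Each row gives an FPKM value (fragments per kilobase of transcript scaled by the number of mapped fragments), the lower and upper bound of its interval in FPKM, and a status, per the file headers. The deposited length column, another unit, equals the genomic span of the locus in base pairs in 99.97% of rows and is not the transcript length. TopHat2 2.0.7, Cufflinks 2.1.1 and the genome build hg18 are named in the submitters' processing notes. Whether a sequence bias correction, a mask for abundant RNA or a correction for multiply mapped reads was used is not given in the sources used here. The symbols of 64 rows had become date numbers and those of 411 rows were missing. Of these rows, 67 received a symbol through their RefSeq accession and 408 were kept under the accession. Rows were summed by symbol into 23881 genes, 8351 of which had more than 1 row.

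In many rows the FPKM lies outside its own interval, in 6219, 5296, 3683 and 2426 rows of the 293T monolayer, MCF-7 monolayer, 293T sphere and MCF-7 sphere tables. Across 3225 genes with 1 row, a locus of 300 bp or more, a GC value, and an FPKM above 0 and an interval midpoint above 2 FPKM in every library, the log2 ratio of FPKM to interval midpoint followed transcript GC content with Spearman correlations of -0.88, -0.88, -0.84 and -0.74 in the same order. These correlations are across genes, which are not independent replicates. The deposited FPKM and intervals thus differ by a GC-dependent factor whose strength differs between libraries, and which of them carries it is not shown. For this reason each ratio was also computed from interval midpoints and after GC centring, both chosen after seeing the data. GC centring subtracted the median log2 ratio at a gene's transcript GC, interpolated between 20 bins that were fitted on genes at 1 FPKM or more in both libraries. It was subtracted from every gene, also from those near or under 1 FPKM, where the pseudocount damps the ratio and centring can overcorrect. ALDH1A1 and UTF1, at 0 FPKM in both MCF-7 libraries, thereby received MCF-7 values of 0.84 and -1.24. Transcript GC and length came from GENCODE 29 transcripts matched by RefSeq accession, or by symbol to the mean of the protein-coding transcripts where no accession matched. With both, 97.2% of genes at 1 FPKM or more in any library had a value. No coordinate was taken from that annotation. Coordinates are those of the files, in hg18, written with a 1-based start.

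The files hold no counts. The width of the deposited intervals, 2 SD to either side, implies a median of 16.1 M fragments (M, mega) in the 293T monolayer library (quartiles 13.7 and 18.1), 5.43 M in the MCF-7 monolayer library (4.65 and 6.15), 4.90 M in the 293T sphere library (4.23 and 5.58) and 3.50 M in the MCF-7 sphere library (3.06 and 3.97). At 5 to 10 FPKM the median half-width was 10.8%, 19.0%, 18.7% and 23.0% of the value in these libraries. The ± printed beside a log2 ratio is the half-width that follows from the deposited intervals of both libraries, scaled to the FPKM. It covers counting and read assignment within a library and no difference between cultures.

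With 1 library per group no test was run and no p-value is given. The log2 ratio of (FPKM + 1) was computed for sphere against monolayer in each line and for MCF-7 against 293T in each format. Ratios on this scale understate the change of genes near 1 FPKM. A gene was tested where it reached 1 FPKM in at least 1 of both libraries, and counted where the ratio was at least 2-fold. The 42 gene lists, the size rule and the rule for named genes were fixed before the data were examined. For a list, the members at least 2-fold higher or lower were counted, and the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on decile of mean expression. The percentile describes these libraries and is not a test of the culture conditions.

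Genes were named by rule. In each line these were the 12 highest and 12 lowest ratios among genes of at least 5 FPKM in the higher library. For both lines these were up to 10 per direction that were 2-fold changed in the same direction and up to 5 per opposed direction, ranked by the smaller ratio. Members of each list that were 2-fold changed could be named, as could up to 4 members with the largest ratios. A fixed panel of 16 stem cell and lineage genes was always named, and for line against line in monolayer the 10 highest and 10 lowest. Small RNA, uncharacterised, antisense, intronic and sex-specific genes, ribosomal protein pseudogenes, loci under 300 bp and genes with a failed status were left out of the ranking. A second ranking, chosen after seeing the data, kept genes at 1 FPKM or more in both libraries whose locus overlaps no other listed locus, and ordered them by the smallest of the FPKM, midpoint and GC-centred ratios. Here and below, overlap was judged between loci of 300 bp or more, with 1 locus per gene, that of its most abundant row. Overlaps with shorter loci or with a gene's other rows were not checked. Genes with near-identical copies, such as histones, HLA genes, IFITM genes and CD24, and genes with overlapping loci share reads, and their values are uncertain.

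The alternatives fixed beforehand were pseudocounts of 0.1 and 5, a filter at 5 FPKM, no filter, 4 rescalings, the largest row per symbol, leaving out loci under 300 bp, and requiring intervals that do not overlap. The functions were tested on simulated counts drawn from the mean FPKM and depth of each pair. Changes were seeded only in genes with a mean of at least 5 FPKM. Recovery of lower genes, where the pseudocount damps the ratio, was therefore not tested. In the simulated MCF-7 pair, 199 of 200 genes seeded with a 4-fold change were recovered by the 2-fold rule, and 36 of 11183 unchanged genes passed it by counting error. In the simulated 293T pair these numbers were 200 of 200 and 8 of 11808. With a GC trend imposed on the simulated MCF-7 pair, 820 of 11285 unchanged genes passed before GC centring and 47 after it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.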

Results

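Expression profiles were compared between adherent monolayers and suspended spheres of 293T and MCF-7 cells, to ask how properties of cancer stem cells (CSCs) differ between the culture formats. Each of the 4 groups is 1 library, so no difference reported here has a replicate check, and higher and lower describe libraries. At 1 FPKM or more the 293T monolayer library held 12153 genes, the MCF-7 monolayer library 11350, the 293T sphere library 11640 and the MCF-7 sphere library 10385. The FPKM sums were 1216878, 1451712, 748189 and 1272670. Loci under 300 bp made up 50.5%, 58.7%, 30.9% and 37.0% of these sums.

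In 293T spheres, CD44, a hyaluronan receptor used as a CSC marker, was higher than in monolayer, at 14.3 against 1.41 FPKM (log2 ratio 2.67 ± 0.27). The reprogramming factor KLF4 stood at 10.4 against 1.503 FPKM (2.18 ± 0.27), POU5F1 at 3.74 against 1.14 FPKM (1.14 ± 0.46) and the efflux transporter ABCG2 at 1.66 against 0.285 FPKM (1.05 ± 0.39). Of 17 measured stem cell and CSC surface or enzyme markers, 4 were at least 2-fold higher, CD44, CXCR4, KIT and ABCG2, and 3 were lower, CD24, MET and LGR5. Their median log2 ratio was 0.48, at percentile 96.1 of random lists, and it turned to -0.09 under upper-quartile scaling. CD24 was 0.382 against 1.82 FPKM, and its reads are shared with near-identical copies. Among 13 pluripotency factors 2 were higher and none lower, with a median of 0.65 at percentile 98.2 (0.03 under upper-quartile scaling). SOX2 was 1.55 against 2.42 FPKM, and NANOG was listed at 0 against 0.555 FPKM. MYC was 61.1 against 38.5 FPKM (0.65 ± 0.11) and VIM 262 against 167 FPKM. EPCAM was 1.82 against 0.981 FPKM, CDH1 2.5 against 0.987 FPKM, ITGA6 2.44 against 2.46 FPKM and ALDH1A3 0.533 against 1.95 FPKM. PROM1, ALDH1A1 and ESR1 stayed under 0.2 FPKM in both 293T libraries.

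Immediate early and ERK feedback genes, which growth factor signalling induces, were the list with the highest median in 293T spheres. Of 27 measured members, 16 were at least 2-fold higher and none lower, with a median log2 ratio of 1.30 at percentile 100. The transcription factor FOS stood at 95.8 against 10.2 FPKM (3.11 ± 0.15), EGR1 at 184 against 39.9 FPKM, IER2 at 79.5 against 16.7 FPKM and the phosphatase DUSP1 at 30.7 against 8.40 FPKM. ETV4 and ETV5, transcription factors downstream of FGF receptors, were 19.8 against 0.378 FPKM and 7.60 against 0.278 FPKM, and SPRY1, a feedback inhibitor of receptor signalling, was 9.99 against 2.98 FPKM. Cyclin D1 (CCND1) was 12.8 against 2.501 FPKM.

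Of 24 cholesterol synthesis and uptake genes 6 were higher in 293T spheres and 1 lower, with a median of 0.55 at percentile 99.97. The median depended on the scaling, at 0.003 under upper-quartile scaling and 1.21 after rescaling to equal sums. INSIG1, which holds back the sterol-regulated transcription factors, was 193 against 38.4 FPKM (2.30 ± 0.10), HMGCS1 43.3 against 14.3 FPKM, SQLE 43.1 against 14.5 FPKM, SREBF2 39.3 against 11.2 FPKM and the LDL receptor gene LDLR 17.4 against 7.07 FPKM. The member that was lower, ACAT2, was listed at 0 in the sphere library. NF-kB and chemokine genes had 5 of 10 members higher and none lower (median 0.90, percentile 99.8), among them CCL5 at 180 against 54.9 FPKM and TNF at 3.44 against 0.0563 FPKM. In the epithelial junction and keratin list 3 of 16 were higher and none lower (0.68, percentile 99.8), with KRT18 at 77.0 against 32.7 FPKM. The luminal breast identity list had 6 of 16 higher and none lower (0.79, percentile 99.96), led by TFF1 at 22.3 against 2.496 FPKM. Under upper-quartile scaling these 3 medians were 0.57, 0.13 and 0.40. In the MCF-7 sphere library TFF1 stood at 14577 FPKM, so the 293T sphere level is 0.153% of it.

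Of 20 replication-dependent histone genes 9 were at least 2-fold lower in 293T spheres and 1 higher, with a median of -0.92 at percentile 0.0 (-0.23 after rescaling to equal sums). HIST1H3B was 19.2 against 67.6 FPKM and HIST1H4H 38.7 against 136 FPKM, and members of this family share reads. The BMP-responsive factors ID1, ID2 and ID3 in the TGF-beta target list were also lower, ID3 at 1.40 against 14.4 FPKM (-2.68 ± 0.58), while BHLHE40 and JUNB of the same list were higher. That list counted 3 higher and 4 lower of 13 (median -0.03, percentile 33.0, and 0.48 after rescaling to equal sums). Mitotic genes had 2 higher and 3 lower of 27 (-0.01, percentile 50.9, and 0.66 after rescaling to equal sums) and DNA replication genes 1 higher and none lower of 27 (0.14, percentile 88.0, and -0.43 under upper-quartile scaling). CDK1 was 66.8 against 31.4 FPKM and CCNE1 5.38 against 23.5 FPKM. Hypoxia response genes had 5 higher and 1 lower of 22 (0.28, percentile 87.2, and -0.29 under upper-quartile scaling), among them the glucose transporter SLC2A3 at 16.1 against 1.05 FPKM and NDRG1 at 54.9 against 9.93 FPKM.

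Other lists in 293T spheres had medians between -0.37 and 0.65, and most changed sign with upper-quartile scaling or rescaling to equal sums. Upper-quartile scaling changed the sign of 24 of all 40 list medians in 293T, and median centring that of 4. Interferon-stimulated genes had 4 higher and none lower of 21 (0.42, percentile 96.9, and -0.03 under upper-quartile scaling), integrins 1 and none of 14 (0.53, percentile 96.8, and 0.02), and Wnt targets 2 and 2 of 11 (0.65, percentile 97.7, and 0.08). Glycolysis genes had 3 and 1 of 18 (0.29, percentile 97.7) and ribosomal protein genes 4 and 3 of 40 (0.11, percentile 98.9), and both medians turned negative under upper-quartile scaling, at -0.28 and -0.47. Counts of higher and lower members were 3 and none of 17 for mesenchymal genes (0.06, percentile 45.1), 3 and none of 14 for fatty acid synthesis (0.36, percentile 90.6), 5 and 1 of 20 for oestrogen receptor targets (0.12, percentile 69.0) and 1 and 3 of 20 for 293T and neural-like markers (-0.06, percentile 24.9), and the positive medians turned negative under upper-quartile scaling and the negative one positive after rescaling to equal sums. They were 1 and none of 28 for YAP/TEAD and SRF targets (0.29, percentile 93.9), none and 1 of 13 for Notch and Hedgehog targets (0.21, percentile 75.4), 1 and none of 22 for ATF4 targets (0.19, percentile 93.0) and none and 3 of 18 for the ER unfolded protein response (-0.36, percentile 11.01), with the same changes of sign. Cytosolic heat shock genes had 3 and 2 of 13 (-0.37, percentile 20.2), NRF2 and oxidative stress genes 1 and 3 of 22 (0.14, percentile 85.6), metallothionein and zinc genes none of 6 (0.16, percentile 64.0) and iron genes 1 and none of 8 (0.43, percentile 91.3), again with these changes of sign. For p53 targets the counts were 2 and 3 of 23 (0.07, percentile 54.3), for apoptosis regulators 2 and 3 of 19 (0.13, percentile 62.6), for glucocorticoid and progesterone receptor targets 1 and 1 of 14 (0.24, percentile 78.5) and for retinoid targets 2 and 1 of 10 (0.08, percentile 60), and all 4 medians turned negative under upper-quartile scaling. Extracellular matrix genes had 1 and none of 20 (0.26, percentile 79.7), ABC transporters 2 and 1 of 10 (0.31, percentile 80.6), growth factor receptors and ligands 2 and 3 of 18 (0.38, percentile 89.0), autophagy and lysosome genes none and 2 of 21 (0.03, percentile 54.2), oxidative phosphorylation genes none of 30 (-0.04, percentile 75.5) and reference genes none and 1 of 25 (0.07, percentile 84.8), where upper-quartile scaling turned the positive medians and rescaling to equal sums the negative one. GC centring also turned the sign of the 293T medians of mesenchymal, autophagy and reference genes and of TGF-beta, oestrogen receptor, p53 and retinoid targets. The mitotic median was 0.22 with midpoints, and the NRF2 and Notch medians were -0.06 and -0.13 with midpoints and GC centring together. Few markers of other cell types were measured, 2 of 11 fibroblast genes, neither 2-fold changed, and 3 of 13 leukocyte and erythroid genes with 1 higher and 1 lower (0.32, percentile 70.7). Of the 12 mitochondrially encoded mRNAs listed, none was measured.

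In all, 1315 of 13064 tested genes were at least 2-fold higher and 1905 at least 2-fold lower in 293T spheres, and 1006 and 1334 of these also passed with interval midpoints and after GC centring. Of the lower genes 734 were listed at 0 in sphere, and of the higher genes 150 in monolayer. The sphere library had the lower implied depth, 4.90 against 16.1 M fragments, so a low gene at 0 there may have been missed. Without loci under 300 bp, 1282 genes were higher and 1672 lower. Higher genes made up 40.8% of the calls with all loci, against 13.5% under upper-quartile scaling (558 higher, 3583 lower) and 80.01% after rescaling each library to an equal sum (4190 higher, 1047 lower). These scalings moved the median of all tested genes by -0.50 and 0.61 on the log2 scale, and rescaling without the 20 most abundant genes moved it by 0.17. Median centring moved it by -0.08 (1121 higher, 2094 lower). The genes above 0 that set the upper quartile depend on depth, and 18732 rows were at 0 in monolayer and 26249 in sphere. How much of the upper-quartile shift comes from this was not tested. Ranked by ratio, the 12 highest genes were all listed at 0 in monolayer, and the locus of each overlaps another listed locus. They were EEF1E1 at 111 FPKM in sphere, HNRNPA1P10 at 62.4 FPKM, RPAIN at 49.4 FPKM, NUP88 at 45.3 FPKM, TAF6 at 42.1 FPKM, GPN1 at 33.8 FPKM, NIT1 at 25.8 FPKM, DEDD at 23.6 FPKM, NFS1 at 22.1 FPKM, C7orf55-LUC7L2 at 21.8 FPKM, WDR83 at 20.7 FPKM and TMEM189-UBE2V1 at 20.1 FPKM. Of the 12 lowest, 11 were listed at 0 in sphere and 9 overlap another locus. In monolayer HYPK stood at 285 FPKM, the histone variant gene H3F3A at 256 FPKM, FAM166A at 141 FPKM, ANAPC15 at 74.3 FPKM, C7orf55 at 58.3 FPKM, SEPTIN2 at 56.2 FPKM, OVCA2 at 54.2 FPKM, PPAN at 41.4 FPKM, CMC2 at 37.7 FPKM, RBM14-RBM4 at 29.2 FPKM and RAD9A at 28.9 FPKM. NRSN1 was 0.0762 against 50.9 FPKM. Among genes at 1 FPKM or more in both libraries and free of overlapping loci, a ranking chosen after seeing the data, the highest were GPR50 at 48.6 against 2.54 FPKM (3.81 ± 0.25), the phosphatase-family gene MTMR12 at 50.03 against 5.12 FPKM, FOS, and PHLDA2 at 34.7 against 3.19 FPKM. The lowest were LMLN at 1.76 against 60.3 FPKM (-4.47 ± 0.23), POP5, a subunit of ribonuclease P, at 1.85 against 51.1 FPKM, and CACNG8 at 1.49 against 24.7 FPKM.

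**Figure D1:**
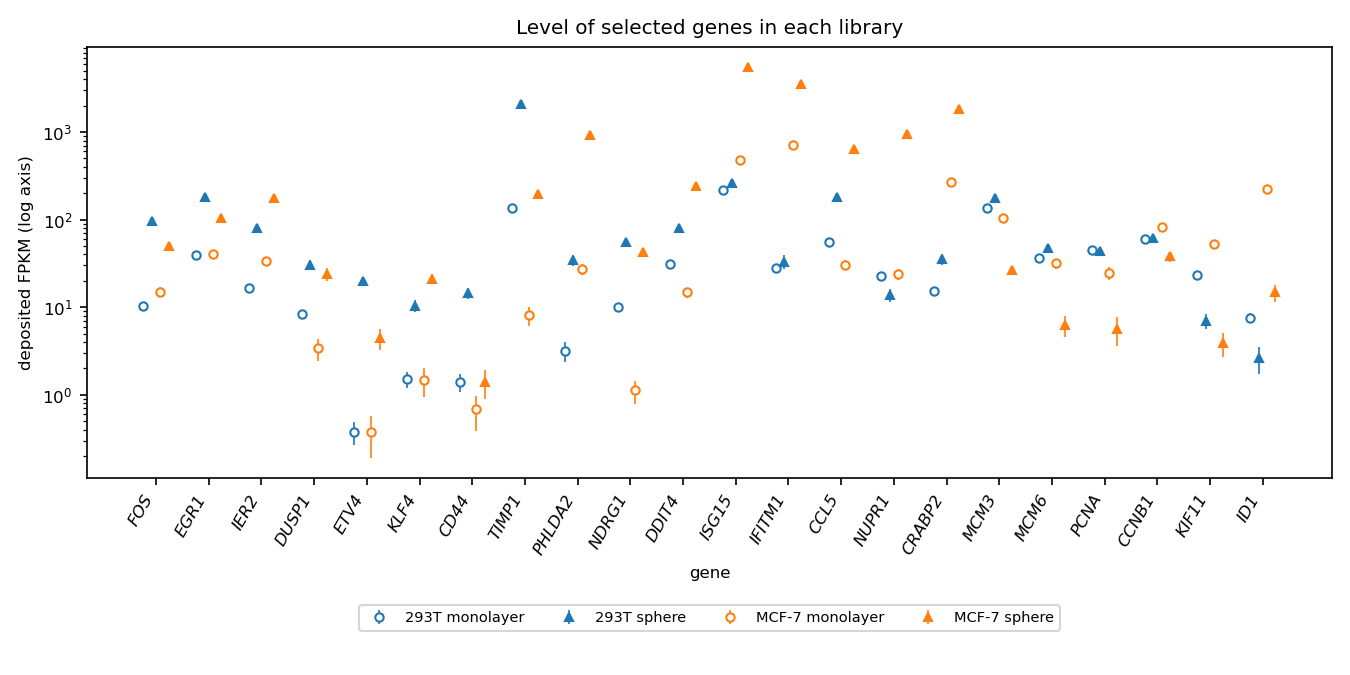
Deposited FPKM on a log axis (y) of 22 genes (x) in the 4 libraries, chosen after the data were seen. TIMP1 and PHLDA2, which rank among the highest in both lines, are on none of the lists, and the other genes are list members. Open circles are monolayers, filled triangles spheres, blue 293T and orange MCF-7. Bars are half-widths of the deposited intervals scaled to the FPKM. FOS stands at 10.2 and 95.8 FPKM in 293T monolayer and sphere, and MCM3 at 105 and 26.8 FPKM in MCF-7 monolayer and sphere.

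In MCF-7 spheres, most measured inflammatory and interferon genes were higher, and most DNA replication genes lower, than in monolayer. Of 12 NF-kB and chemokine genes, 9 were at least 2-fold higher and 1 lower, with a median log2 ratio of 2.30 (2.18 after GC centring), both at percentile 100. The chemokine gene CCL5 stood at 633 against 30.4 FPKM (4.34 ± 0.18), the siderophore-binding protein gene LCN2 at 72.6 against 2.52 FPKM, ICAM1 at 24.7 against 0.613 FPKM and NFKBIA, which inhibits NF-kB, at 314 against 61.5 FPKM. Of 27 interferon-stimulated genes, 15 were higher and 1 lower, with a median of 1.13 (1.5002), at percentiles 99.98 and 100. ISG15, a ubiquitin-like modifier, was 5490 against 478 FPKM (3.52 ± 0.06), and IFITM1 3499 against 713 FPKM. IFI6 was 1811 against 362 FPKM and the transcription factor gene IRF1 45.1 against 6.37 FPKM.

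GC-centred values are given beside the MCF-7 list medians because the ratio in this line followed transcript GC content. Across 9120 genes at 1 FPKM or more in both libraries, its Spearman correlation with GC was 0.63, and the median log2 ratio ran from -0.99 in the sixth of genes lowest in GC to 1.04 in the highest. With interval midpoints the correlation was 0.43. In 293T it was 0.05 with FPKM and -0.11 with midpoints.

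**Figure D2:**
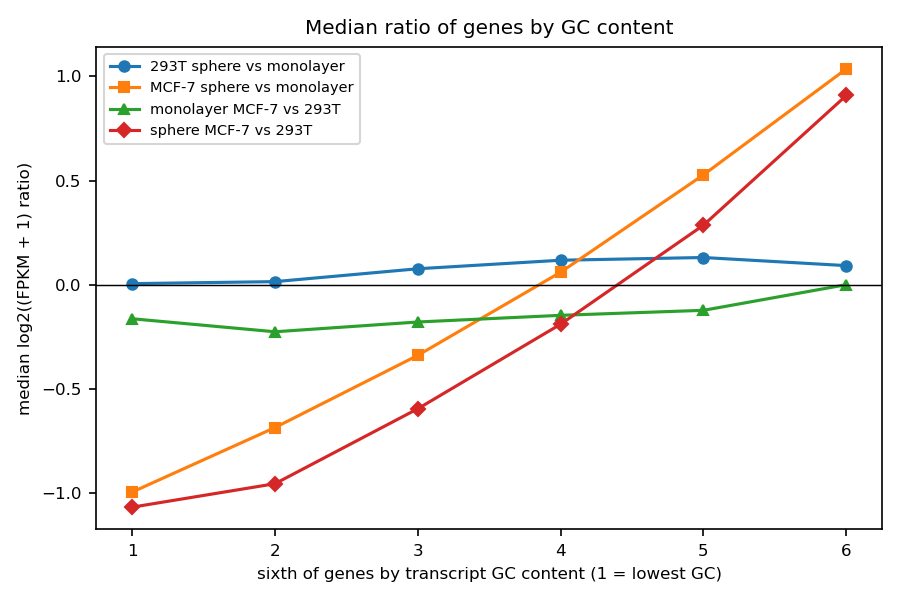
Median log2 ratio of (FPKM + 1) (y) in sixths of genes ordered by transcript GC content (x), for each of the 4 comparisons, 1 line per comparison. Both comparisons with the MCF-7 sphere library climb, from -0.99 to 1.04 against its monolayer and from -1.07 to 0.91 against the 293T sphere, while those between the monolayers lie from -0.22 to 0.0012 and those between the 293T libraries from 0.0061 to 0.13.

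Immediate early and ERK feedback genes had 15 of 23 members higher and 1 lower in MCF-7 spheres, with a median of 1.35 (1.29 after GC centring), both at percentile 100. JUNB was 417 against 61.9 FPKM, IER3 1383 against 326 FPKM, IER5 48.2 against 7.66 FPKM and DUSP4 28.0 against 1.01 FPKM (3.85 ± 0.23). The member that was lower was MYC, at 34.0 against 72.1 FPKM (-1.06 ± 0.18). Retinoid targets had 5 of 6 higher and 1 lower, with a median of 2.39 at percentile 99.99 (2.32 at percentile 100 after GC centring). The retinoid median was 1.34 with a pseudocount of 5, and 0.12 without a filter and with a pseudocount of 0.1. CRABP2, which carries retinoic acid in the cell, was 1832 against 271 FPKM, and RARRES3 was 157 against 9.31 FPKM. Of 13 glucocorticoid and progesterone receptor targets 7 were higher and 3 lower (median 1.40, percentile 99.9, and 1.07 after GC centring), including PER1 at 15.8 against 2.24 FPKM and FKBP5, a lower member, at 3.70 against 17.1 FPKM. This list had a median of 0.82 after rescaling without the 20 most abundant genes, and of -0.21 without a filter and with a pseudocount of 0.1.

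The hypoxia, ATF4 and autophagy lists also had more higher than lower members in MCF-7 spheres, though with FPKM most members of each were not 2-fold higher. The cytosolic heat shock, NRF2 and ER unfolded protein response lists had medians below 0, but the ER median was 0.03 after GC centring and the NRF2 median 0.16 after rescaling to equal sums. Of 21 hypoxia response genes, 9 were higher and none lower, with a median of 0.73 at percentile 99.2 (1.15 at percentile 100 after GC centring). NDRG1 stood at 42.8 against 1.12 FPKM (4.37 ± 0.26), ANGPTL4 at 94.8 against 1.22 FPKM, carbonic anhydrase 9 (CA9) at 15.1 against 0.0456 FPKM, DDIT4 at 241 against 14.8 FPKM and VEGFA at 66.5 against 12.5 FPKM. ATF4 targets had 11 of 23 higher and 3 lower (0.99, percentile 99.8, and 0.71 after GC centring), with NUPR1 at 952 against 23.8 FPKM (5.27 ± 0.20) and ASNS at 71.6 against 25.8 FPKM. The ATF4 median was 0.29 with midpoints and GC centring together, and 0.35 with a pseudocount of 5. DDIT3, which overlaps another locus, was 154 FPKM in sphere and listed at 0 in monolayer. Autophagy and lysosome genes had 9 of 21 higher and 3 lower (0.77, percentile 99.2, and 0.72), among them SQSTM1 at 301 against 65.8 FPKM. For p53 targets the counts were 9 and 4 of 22 (0.45, percentile 94.1, and 0.53 at percentile 99.0), with the cyclin-dependent kinase inhibitor gene CDKN1A at 392 against 46.5 FPKM and GDF15 at 984 against 19.5 FPKM (5.58 ± 0.18). Under upper-quartile scaling the hypoxia, autophagy and p53 medians were 0.32, 0.40 and 0.08.

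Cell cycle lists had more lower than higher members. None of 27 DNA replication genes was at least 2-fold higher in MCF-7 spheres and 18 were lower, with a median of -1.38 (-1.12 after GC centring), both at percentile 0.0. MCM3 and MCM6, subunits of the replicative helicase, were 26.8 against 105 FPKM (-1.93 ± 0.16) and 6.28 against 31.6 FPKM, the sliding clamp gene PCNA 5.70 against 24.7 FPKM and the thymidylate synthase gene TYMS 6.50 against 30.1 FPKM. Of 27 mitotic genes 15 were lower and none higher (-1.11, percentile 0.02), and after GC centring 11 were lower and 1 higher (-0.83, percentile 0.01). CCNB1 was 38.0 against 83.3 FPKM (-1.11, and -0.37 after GC centring) and MKI67 19.8 against 51.0 FPKM (-1.32 and -0.92), so both lost the 2-fold call after GC centring, and the spindle motor gene KIF11 was 3.89 against 53.3 FPKM (-3.47 ± 0.38). Histone genes had 11 of 22 lower and 1 higher (-1.14 at percentile 0.04, and -0.97 at percentile 0.02 after GC centring). In the TGF-beta target list 5 of 13 were lower and 3 higher (-0.70, percentile 9.5, -0.61 at percentile 3.4, and -1.06 under upper-quartile scaling), and ID1 was 14.8 against 223 FPKM (-3.82 ± 0.31). Cytosolic heat shock genes had 7 of 13 lower and 2 higher (-1.19, percentile 0.1), and after GC centring 5 lower and none higher (-0.57, percentile 4.0), with the chaperone genes HSPA8 at 38.8 against 506 FPKM and HSP90AA1 at 188 against 729 FPKM, and HSPB1 at 6936 against 1706 FPKM (2.02, and 0.98 after GC centring).

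Epithelial and luminal lists had medians above 0, with 12 of 28 epithelial genes higher and 3 lower (0.88, percentile 99.5, and 0.54 at percentile 99.0) and 12 of 23 luminal genes higher and 2 lower (1.04, percentile 99.5, and 0.90 at percentile 99.99). After GC centring the counts were 7 and 4, and 9 and 2. Under upper-quartile scaling these medians were 0.52 and 0.67. TFF3 stood at 517 against 17.6 FPKM (4.80 ± 0.25), MUC1 at 707 against 102 FPKM and the serine protease gene PRSS8 at 315 against 15.3 FPKM. Oestrogen receptor targets had 6 higher and 9 lower of 25 (-0.38, percentile 17.1, -0.45 at percentile 2.4, and -0.74 under upper-quartile scaling), with TFF1 at 14577 against 2990 FPKM. GREB1 was at 1.49 against 15.4 FPKM and MYB at 5.06 against 23.7 FPKM. ESR1 was 13.01 against 23.3 FPKM (-0.79 ± 0.19, and -0.23 after GC centring). In the stem cell and CSC marker list 2 of 10 were higher, CXCR4 at 14.9 against 0.671 FPKM and ENG, and 1 was lower, ITGB1. After GC centring 4 were higher and none lower, with CD44 and EPCAM (1.06) joining and ITGB1 (-0.53) leaving. CD44 lay near 1 FPKM, where GC centring can overcorrect. The list median was 0.23 (percentile 81.5, 0.26 at percentile 84.8 after GC centring, -0.20 under upper-quartile scaling and -0.22 after rescaling without the 20 most abundant genes). It was also negative with a filter at 5 FPKM (-0.41), without a filter and with a pseudocount of 0.1 (-0.51) and with the largest row per symbol (-0.06). CD44 was 1.41 against 0.680 FPKM (0.52 ± 0.40, and 1.02 after GC centring) and CD24 17.5 against 30.5 FPKM (-0.77 ± 0.37, and -0.17 after GC centring). EPCAM was 59.0 against 40.9 FPKM and CDH1 38.6 against 31.6 FPKM. ALDH1A1 was listed at 0 in both MCF-7 libraries, and ITGA6 was 0.351 against 0.183 FPKM. ALDH1A3, PROM1 and ABCG2 were listed at 0 in sphere, against 0.248, 0.301 and 0.709 FPKM in monolayer. All of these genes lay under 1 FPKM in both MCF-7 libraries and were not counted as measured. Of 9 pluripotency factors 3 were higher and 1 lower (0.38, percentile 89.5, 0.65 at percentile 96.4 after GC centring, and -0.20 after rescaling without the 20 most abundant genes), KLF4 at 20.99 against 1.48 FPKM (3.15 ± 0.36), KLF2 and SALL4 being the higher ones and MYC the lower. After GC centring 2 were higher and 2 lower, since KLF2 (1.80) was at 0.70 and DNMT3B (-0.99) at -1.20, and the median was -0.30 without a filter and with a pseudocount of 0.1. POU5F1 was 1.96 against 1.28 FPKM, SOX2 3.53 against 2.54 FPKM, NANOG 0.0992 against 0.547 FPKM and VIM 3.80 against 2.57 FPKM.

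Some MCF-7 medians lost their place when the GC trend was removed. Extracellular matrix genes had 9 higher and 2 lower of 12 (1.25, percentile 99.9), and after GC centring 5 and 1 (0.21, percentile 79.7). For ABC transporters the counts were 5 and none of 10 (0.80, percentile 98.0), and after GC centring 4 and none (-0.05, percentile 52.8). Mesenchymal genes had 4 higher and 1 lower of 7 (1.21, percentile 99.1), against 2 and none (0.62, percentile 93.5). Notch and Hedgehog targets had 3 and none of 5 (1.64, percentile 98.8), against 2 and 1 (0.83, percentile 95.1), and oxidative phosphorylation genes 1 and 7 of 30 (-0.44, percentile 1.1), against 3 and 2 (-0.23, percentile 15.9). TGFB1 was 30.1 against 2.77 FPKM (3.04 ± 0.32, and 2.09 after GC centring). YAP/TEAD and SRF targets had 3 and 8 of 26 (-0.33, percentile 27.2), against 1 and 5 with a median further from 0 (-0.54, percentile 0.75), and fatty acid synthesis genes had 6 and 3 of 14 (0.60, percentile 95.6), against 4 and 1 (0.76, percentile 99.3), with SREBF1 at 327 against 34.2 FPKM. Upper-quartile scaling gave medians of 0.49 for ABC transporters, -0.81 for oxidative phosphorylation, -0.70 for YAP/TEAD and SRF targets and 0.30 for fatty acid synthesis, and rescaling without the 20 most abundant genes 0.09 for mesenchymal genes. Negative medians without a filter and with a pseudocount of 0.1 were those of Notch and Hedgehog targets (-0.52), mesenchymal genes (-0.28) and extracellular matrix genes (-0.058).

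Further MCF-7 lists follow with their higher and lower counts, and then with those after GC centring. Cholesterol genes had 4 and 6 of 23 (-0.01, percentile 45.4), then 2 and 3 (0.11, percentile 70.9), with a median of 0.17 after rescaling to equal sums. Glycolysis genes had 7 and 2 of 18 (0.44, percentile 76.2), then 4 and 2 (0.16, percentile 73.3), 293T and neural-like markers 4 and none of 9 (0.52, percentile 90.5), then 3 and 1 (0.32, percentile 85.0), and Wnt targets 1 and 2 of 7 (-0.68, percentile 18.8), then 1 and 3 (-0.45, percentile 15.1). Under upper-quartile scaling these last 3 medians were 0.07, 0.17 and -1.07, and that of the neural-like markers was -0.39 without a filter and with a pseudocount of 0.1. The ER unfolded protein response had 1 and 2 of 18 (-0.27, percentile 17.4), then 3 and 1 (0.03, percentile 58.0), and NRF2 and oxidative stress genes 7 and 6 of 24 (-0.23, percentile 28.0), then 7 and 3 (-0.17, percentile 26.0). Metallothionein and zinc genes had 1 and 2 of 6 (-0.01, percentile 63.3), then 2 and 2 (-0.46, percentile 15.2), and iron genes 2 and 3 of 7 (0.12, percentile 64.9), then 2 and 1 (0.73, percentile 95.4). Rescaling to equal sums gave the NRF2, metallothionein and iron lists medians of 0.16, 0.16 and -0.31, and the iron median was -0.49 with a filter at 5 FPKM. Apoptosis regulators had 5 and 2 of 18 (0.27, percentile 86.2), then 4 and 1 (0.39, percentile 94.2), with BBC3 at 22.4 against 1.30 FPKM, and integrins 5 and 3 of 13 (0.19, percentile 81.7), then 5 and 1 (0.49, percentile 94.6). Growth factor receptors and ligands had 4 and 3 of 15 (0.50, percentile 93.7), then 1 and 2 (0.14, percentile 78.6), and their median was 0.01 at percentile 56.6 with midpoints. Ribosomal protein genes had 2 and 1 of 40 (0.32, percentile 44.8), then 5 and none (0.36, percentile 93.3), and reference genes 3 and 9 of 25 (-0.33, percentile 5.5), then 2 and 4 (-0.41, percentile 5.2). Under upper-quartile scaling the apoptosis, integrin and ribosomal medians were -0.08, -0.15 and -0.05. Leukocyte and erythroid markers had 1 and none of 3 (-0.24, percentile 54.7), then 1 and 1 (0.63, percentile 84.5), and the 1 measured fibroblast gene of 11, COL1A1, was 8.90 against 1.68 FPKM (1.89, and 1.09 after GC centring).

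**Figure D3:**
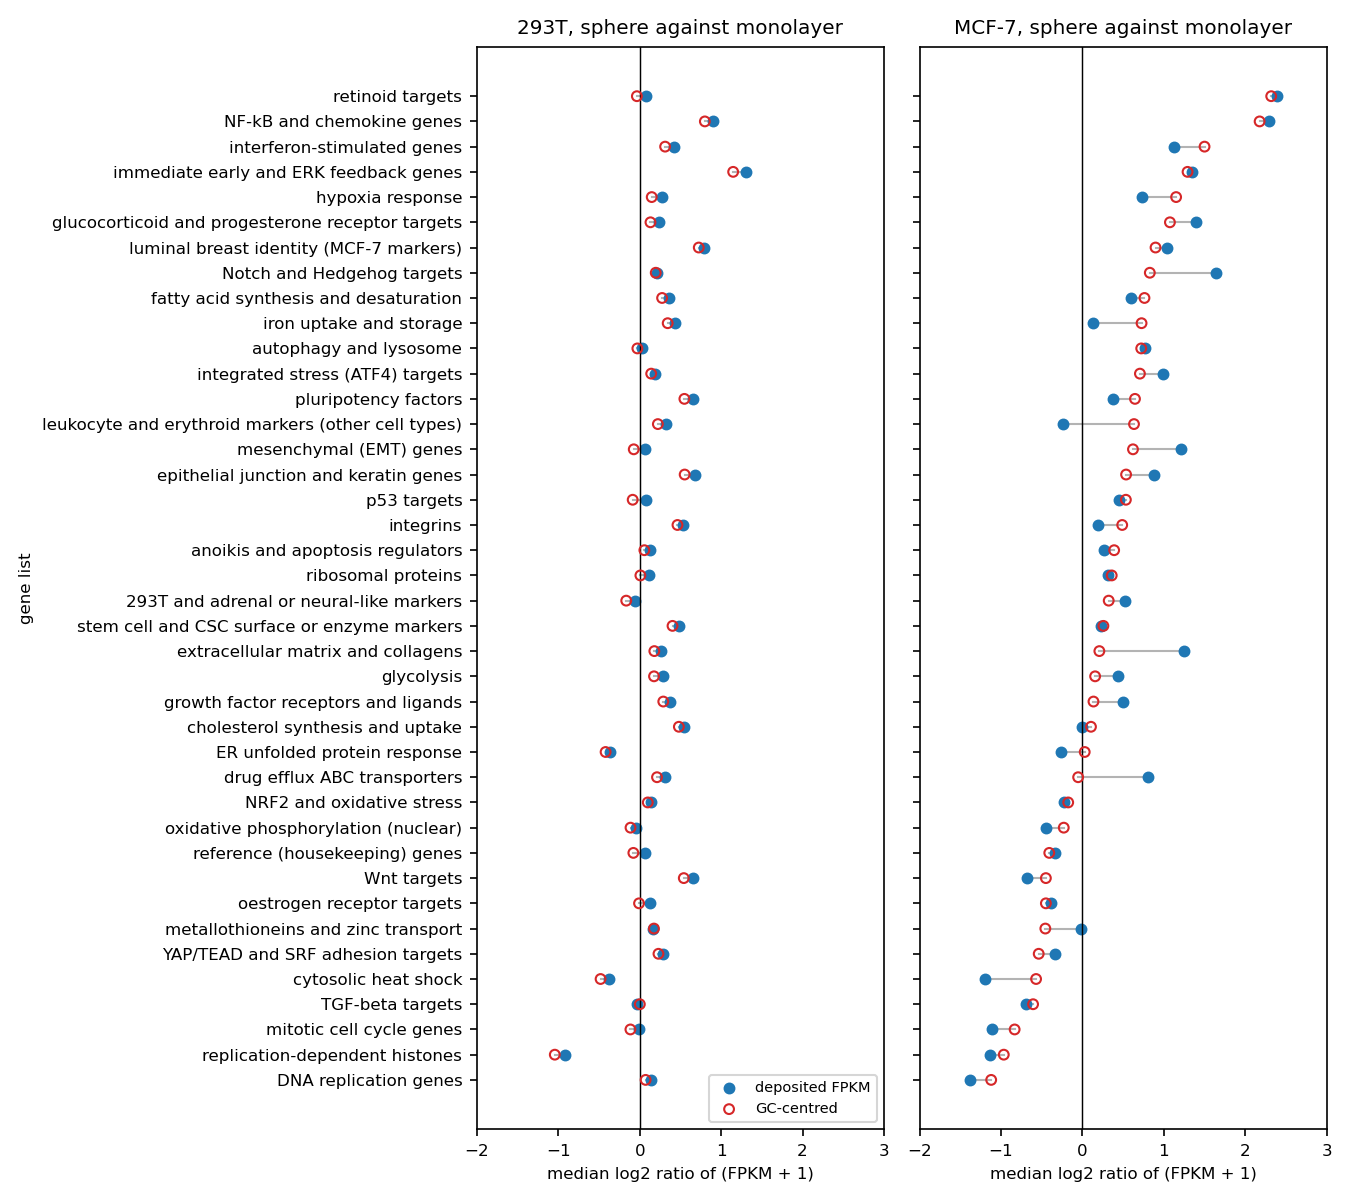
Median log2 ratio of (FPKM + 1), sphere against monolayer (x), of the measured members of 40 gene lists (y) in 293T (left) and MCF-7 (right), with filled blue circles for deposited FPKM and open red circles after GC centring. Immediate early genes lie at 1.30 and 1.35, and DNA replication genes at 0.14 in 293T and -1.38 in MCF-7.

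Across the transcriptome, 2415 of 12437 tested genes were higher and 3408 lower in MCF-7 spheres, a share of higher calls of 41.5%, against 28.0% under upper-quartile scaling (1768 higher, 4539 lower). Of the 3408 lower genes 665 were listed at 0 in sphere, and of the 2415 higher genes 233 in monolayer. After GC centring 1836 were higher and 1817 lower, which kept 1342 and 1493 of the original calls, and 1295 and 1307 passed with FPKM, midpoints and GC centring alike. The median of all tested genes moved by -0.31 under upper-quartile scaling, by 0.16 after rescaling to equal sums, by -0.22 after rescaling without the 20 most abundant genes and by 0.19 with GC centring. By rank the highest were DSCR8 at 301 FPKM in sphere, DDIT3, C19orf33 at 128 FPKM, MGP, an inhibitor of calcification, at 79.2 FPKM, BSCL2 at 78.4 FPKM and VPS9D1 at 46.8 FPKM, all 6 listed at 0 in monolayer. Next came the complement factor B gene CFB at 364 against 3.70 FPKM (6.28 ± 0.34), C1QL1 at 77.4 against 0.364 FPKM and IGFBP6 at 171 against 2.46 FPKM. They were followed by GDF15, LTB at 101 against 1.14 FPKM and PRODH, a proline-degrading enzyme, at 152 against 2.20 FPKM. Of these 12 highest genes, 4 overlap another locus. Of the 12 lowest, 10 were listed at 0 in sphere and 11 overlap another locus. These were HYPK at 463 FPKM in monolayer, PRELID1 at 85.9 FPKM, FDPS at 77.1 FPKM, THOC6 at 75.3 FPKM, FAM133DP at 71.1 FPKM, TLCD1 at 69.8 FPKM, PPAN at 67.2 FPKM, SLMO2-ATP5E at 66.5 FPKM, RFC4 at 45.4 FPKM and CTU2 at 44.2 FPKM. SIAE was 2.32 against 3920 FPKM and NRSN1 0.180 against 82.1 FPKM. In the second ranking, chosen after seeing the data, CFB was followed by the acute phase gene SERPINA3 at 98.0 against 1.66 FPKM, the chemokine gene CCL22 at 92.5 against 1.64 FPKM and S100P at 805 against 17.6 FPKM. The lowest were LYAR at 3.71 against 183 FPKM (-5.29 ± 0.54), RPPH1, the RNA of ribonuclease P, at 112 against 1821 FPKM, and ID1.

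The responses of both lines were then set side by side over 11053 genes tested in each. At least 2-fold higher in both were 298 genes, against 151 if the lists were independent, and lower in both were 703, against 422. After GC centring the numbers were 233 against 95.1 and 463 against 248. The balance of higher and lower depended on the scaling, with 117 higher and 1529 lower in both under upper-quartile scaling and 879 and 329 after rescaling to equal sums. Across genes, which are not independent replicates, the ratios of the lines had a Pearson correlation of 0.32, and the comparisons share no library. Of the 10 genes that rank highest in both, 9 overlap another listed locus, and so do 6 of the 10 lowest. TIMP1, an inhibitor of metalloproteinases (chromosome X, 47326634 to 47331134 in hg18), overlaps another locus and was higher in both, at 2087 against 134 FPKM in 293T (3.95 ± 0.07) and 198 against 8.08 FPKM in MCF-7 (4.45 ± 0.33). PHLDA2 (chromosome 11, 2906079 to 2907226), the gene without an overlap, reached 926 against 27.4 FPKM in MCF-7. The other 8 were all listed at 0 in both monolayers, RPAIN, HNRNPA1P10, DEDD, GPN1, NIT1, ST20, LOXL3 and FAM134C, with LOXL3, a lysyl oxidase family gene, at 8.56 FPKM in 293T spheres and 10.9 FPKM in MCF-7 spheres. Among the 10 lowest in both, 7 were listed at 0 in a sphere library, HYPK, PPAN, HIST1H2AD, EFCAB10, HIST2H3D, GNG10 and MTHFS, and LMLN, NRSN1 and the calcium channel subunit gene CACNG8 had values in all 4 libraries. CACNG8 (chromosome 19, 59158102 to 59185281) was 0.463 against 15.4 FPKM in MCF-7. KLF4 (chromosome 9, 109286954 to 109291868) was higher in both lines, and CD44 (chromosome 11, 35116993 to 35201443) passed the 2-fold rule in 293T.

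Fewer genes than independence gives were 2-fold changed in opposite directions, 159 higher in 293T and lower in MCF-7 (246 if independent) and 191 the reverse (260). After GC centring these were 62 (113) and 169 (209). S100P (chromosome 4, 6746467 to 6749798), a calcium-binding protein gene, was lower in 293T spheres at 0.606 against 6.02 FPKM. ETHE1, a mitochondrial sulfur dioxygenase gene, was 2.74 against 20.0 FPKM in 293T and 82.4 against 9.99 FPKM in MCF-7. TEKT4 (0.904 against 13.7 FPKM in 293T, 49.1 against 9.25 FPKM in MCF-7) and ATP6V1D (2.89 against 14.8 FPKM, 47.6 against 12.1 FPKM) had the same directions, as did LY6G6D, listed at 0 in 293T sphere and MCF-7 monolayer. Higher in 293T and lower in MCF-7 were PANK3, at 25.2 against 6.10 FPKM and 0.410 against 7.73 FPKM, PPIL1, at 66.2 against 18.1 FPKM and 1.13 against 11.2 FPKM, and UBE2F-SCLY, listed at 0 in 293T monolayer. TEKT4 and UBE2F-SCLY overlap another listed locus. COMMD8 and CETN3 were named by the same rule, with MCF-7 ratios of -1.999 ± 1.03 and -1.99 ± 1.08 that were -0.87 and -0.85 after GC centring. The median difference between the lines, MCF-7 minus 293T on the log2 scale, was -1.64 for DNA replication genes and -1.16 for mitotic genes (-1.16 and -0.82 after GC centring). It was 1.16 for interferon-stimulated genes and 1.37 for NF-kB and chemokine genes (1.62 and 1.10), and 0.15 for immediate early genes (-0.02). None of these differences could be tested with 1 library per group.

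Line against line, the monolayers differed in genes of each lineage. Luminal genes led in MCF-7, with TFF1 at 2990 against 2.496 FPKM, the keratin genes KRT19 at 1597 against 1.80 FPKM and KRT8 at 3993 against 26.5 FPKM, and the transcription factor gene SPDEF at 212 against 0.147 FPKM. ADIRF stood at 258 FPKM and was listed at 0 in 293T. CLDN3 was 159 against 0.259 FPKM, TSTD1 139 against 0.106 FPKM, and IFI27 473 against 2.94 FPKM. S100A14 was 87.3 against 0.0421 FPKM and the DNA repair gene MGMT 79.4 against 0.0236 FPKM. Higher in 293T were the glutathione transferase gene GSTP1 at 408 against 0.488 FPKM, UCHL1 at 171 against 0.289 FPKM, and LDHB at 485 against 3.08 FPKM. So were the tumour suppressor gene CDKN2A at 184 against 0.574 FPKM, SIGMAR1 at 115 against 0.151 FPKM and GPX1 at 246 against 1.75 FPKM. NME1 at 561 FPKM, H3F3A, SERF2-C15ORF63 at 125 FPKM and PDIA3 at 75.9 FPKM were listed at 0 in MCF-7. Of these genes higher in 293T, UCHL1 alone is on the list of 293T and neural-like markers. Overlap with other loci was not counted for this comparison. A gene listed at 0 here, ADIRF included, is therefore not shown to be absent from that line. In monolayer 1493 of 13272 genes were higher in MCF-7 and 2559 lower, and in sphere 2980 of 13107 were higher and 5029 lower, a share of higher calls of 36.8% and 37.2%. The median moved by 0.13 with median or GC centring and -0.20 after rescaling to equal sums between the monolayers, and by 0.32, 0.41 and -0.62 between the spheres, where upper-quartile scaling moved it by 0.18 and leaving out the 20 most abundant genes by -0.43. The sphere share was 47.9% with median centring, 49.0% with GC centring and 21.9% after rescaling to equal sums. The Spearman correlation of ratio and GC was 0.09 between the monolayers and 0.50 between the spheres.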

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

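The tests on interval midpoints, on which library carries the GC trend and on the luminal genes were chosen after the results were seen, and those on abundant genes and on genes listed at 0 after the pattern but before their own values.

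The lines differed in direction, untested with 1 library per group, for 350 genes at least 2-fold changed in opposite directions. By direction these were 159 and 191, fewer than the 246 and 260 that independence gives. The count of 350 was 231 after GC centring, 217 with midpoints as well, 98 with a pseudocount of 5 and 1165 without a filter and with a pseudocount of 0.1. The median difference, MCF-7 minus 293T on the log2 scale, was -1.68 for Wnt targets and -0.34 for YAP/TEAD and SRF targets, over the 6 and 24 members measured in both lines. The 6 Wnt members include MYC, CCND1 and CD44, which also belong to other lists. The MCF-7 medians of all measured members lay at percentiles 18.8 (Wnt) and 27.2 (YAP/TEAD and SRF), and at 15.1 and 0.75 after GC centring. In these lists the medians of the lines had opposite signs and a size of at least 0.2 with FPKM, midpoints and GC centring, a limit set after the medians were seen. The opposition depends on the scaling, since under upper-quartile scaling the 293T medians of all measured members were 0.08 for Wnt and -0.12 for YAP/TEAD and SRF targets. By gene the difference was 7.57 for S100P, 6.64 for LY6G6D, 5.41 for ETHE1, 5.23 for TEKT4, 3.91 for ATP6V1D, -5.26 for UBE2F-SCLY, -4.51 for PANK3 and -4.33 for PPIL1, each opposed by at least 2-fold with all 3 kinds of value.

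A signal outside the gene lists, but inside the FPKM sums used for rescaling, came from MIR4461, a 74 bp locus on chromosome 5 (134291628 to 134291701, hg18). Its FPKM was 525995 in 293T monolayer, 687261 in MCF-7 monolayer, 154227 in 293T sphere and 388426 in MCF-7 sphere. These values are 182, 189, 162 and 175 times the midpoints of their own intervals, and 43.2%, 47.3%, 20.6% and 30.5% of the FPKM sums.

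The first pattern weighed is the GC trend of the MCF-7 ratios. The GC-dependent factor by which FPKM and interval midpoint differ is argued against as its whole cause by a Spearman correlation of 0.43 with midpoints and 0.63 with FPKM, while a GC bias that both kinds of value share stays open. The lower depth of the MCF-7 sphere library is argued against by a correlation of 0.54 among the 2017 genes at 20 FPKM or more in both libraries. The trend may be carried by the MCF-7 sphere library alone, since the correlation was 0.50 between the sphere libraries, 0.09 between the monolayers and 0.05 between the 293T libraries. Whether a bias of that library or the state of MCF-7 cells in sphere culture underlies it stays open, because that library is the whole group.

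The second pattern is genes of at least 5 FPKM in one library and listed at 0 in the other, 163 in 293T and 176 in MCF-7 among loci of 300 bp or more. Too few reads is argued against by the median number of fragments expected at the other library's level, 142 in 293T and 87.3 in MCF-7 (138 and 152 genes with a transcript length). The locus overlaps another listed locus for 81.0% and 72.7% of these genes, against 18.0% and 17.6% of other genes at 5 FPKM or more, at least 4.13 times as often. Assignment of reads to an overlapping locus is therefore a candidate explanation for many of the largest ratios, while an overlap excludes no real difference at a single gene and the genes without an overlap stay unexplained.

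The third pattern is the 6 luminal breast genes at least 2-fold higher in 293T spheres, GATA3, TFF1, KRT18, KRT19, SPDEF and EFHD1. All 6 log2 ratios exceed their own half-width, but the genes were chosen for a ratio of at least 2-fold, which favours that outcome. The ratio was 1.21 ± 0.14 for KRT18, 1.80 ± 0.41 for KRT19 and 2.74 ± 0.59 for TFF1. Counting error is argued against for these 3 genes only. MCF-7 RNA or reads in the 293T sphere library would have to equal 1.30% of the MCF-7 sphere level for KRT18 and 23.0% for EFHD1, while the whole TFF1 signal amounts to 0.153%, and 11 other genes, at 50 FPKM or more in both MCF-7 libraries and under 0.5 FPKM in 293T monolayer, gave a median share of 0.104%, 0.146 times the median need of the 6 (quartiles -0.0144% and 1.60%), or 0.0546% and 0.0767 times without FUS and PLCG1, which belong to the second pattern in 293T and were left out after their values were seen. For TFF1, KRT19 and SPDEF alone the ratio was 0.764, or 0.401 without FUS and PLCG1, but the quartiles span 0 either way (-0.0173% and 0.347% without them), a point raised after the value was seen, so that a trace of MCF-7 material and a response of 293T cells cannot be told apart for these 3 genes. The culture format, as a biological cause, stays open and untested for all 6.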

How the results depend on the processing

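Interval midpoints and GC centring, alone or together, were chosen after seeing the data, and the other alternatives before. Of 167 counts and correlations under an alternative, 116 stayed near the reported value and 51 did not. Near meant within 1.5 times for a count, and within a fixed difference for a correlation. Of 1040 gene list medians under an alternative, 945 kept their sign and 95 changed it, 24 of these in 293T under upper-quartile scaling. Only 8 of the 95 belong to a list whose reported median lies in the lowest or highest 2.5% of random lists. Of the other medians 956 lay within the half-width of the reported median's bootstrap interval and 76 beyond it. That interval resamples the members of a list, so it covers the spread between genes and no difference between cultures. A median within it may still have changed sign. Of 1486 values of named genes 13 changed sign, 2 of them for a gene at least 2-fold changed, and of the others 793 lay within the half-width of the reported ratio and 691 beyond it. Sphere and monolayer could be paired within a line, but this gives only 2 pairs, and no paired analysis or test was run.

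With a pseudocount of 0.1, 1980 genes were higher in 293T spheres, 509 higher in both lines and 580 opposed. A pseudocount of 5, which shrinks ratios of low genes by construction, left 375 higher and 769 lower in 293T, 1390 and 1458 in MCF-7, 83 higher and 284 lower in both, 98 opposed, 781 and 1031 between the monolayers and 1816 and 2509 between the spheres. A filter at 5 FPKM, which tests fewer genes, left 857 and 1131 in 293T, 2255 lower in MCF-7, 178 higher and 429 lower in both, 185 opposed and 1634 lower between the monolayers. No filter with a pseudocount of 0.1, which tests more genes, gave 2281 and 4879 in 293T, 6800 lower in MCF-7, 643 higher and 2179 lower in both, 1165 opposed, 2985 and 4597 between the monolayers and a correlation of 0.22 between the lines.

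Upper-quartile scaling gave 558 and 3583 in 293T, and 117 higher and 1529 lower in both. Rescaling to equal sums gave 4190 and 1047 in 293T, 879 and 329 in both and 565 opposed, and rescaling without the 20 most abundant genes 2302 higher in 293T, 465 higher in both and 631 opposed. GC centring gave 1817 lower in MCF-7, 463 lower in both, 231 opposed and 3170 lower between the spheres, and with midpoints as well 1885, 457, 217 and 2966. Of the 1817 and 3170 lower genes, 1493 and 2861 were lower before GC centring too. Midpoints alone gave 460 lower in both. Rescaling to equal sums includes loci under 300 bp, among them MIR4461 at 525995 and 154227 FPKM in 293T monolayer and sphere. The 293T sums were 1216878 and 748189 FPKM with such loci, and 602038 and 516879 FPKM without them. These loci thus make up most of the difference that this rescaling removes in 293T. For the other scalings, midpoints and GC centring the cause was not tested.

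Of the 8 medians in the lowest or highest 2.5% that changed sign, those in MCF-7 without a filter and with a pseudocount of 0.1 were of mesenchymal genes (-0.28), Notch and Hedgehog targets (-0.52), glucocorticoid and progesterone receptor targets (-0.21) and extracellular matrix genes (-0.058). The others were the 293T medians of glycolysis (-0.28) and ribosomal protein genes (-0.47) under upper-quartile scaling, and that of ABC transporters in MCF-7 with GC centring (-0.052) and with midpoints as well (-0.18). With midpoints and GC centring the 2-fold changed genes COMMD8 (0.35) and CETN3 (0.21) changed sign in MCF-7. The cause was not tested. Depth limits the MCF-7 sphere library most, with a median half-width of 23.0% at 5 to 10 FPKM, against 10.8% in 293T monolayer.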

Other observations

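The gene groups in this part were all chosen after the data were seen, and no percentile among random lists was computed for them. In MCF-7 spheres all 13 measured S100 genes, which encode small calcium-binding proteins, were at least 2-fold higher than in monolayer, with a median log2 ratio of 2.18, and 12 remained so after GC centring. S100A9 stood at 1914 against 61.6 FPKM (4.93 ± 0.26), its partner S100A8 at 363 against 13.2 FPKM (4.68 ± 0.57), S100A7 at 529 against 17.6 FPKM (4.83 ± 0.67) and S100A6 at 839 against 84.8 FPKM. In 293T spheres 5 of 9 measured members were higher and 1 lower, and S100A7 and S100A8 were listed at 0. Genes of MHC class I and antigen processing had 9 of 11 measured members higher and none lower in MCF-7 spheres (median 2.02, and 1.73 after GC centring), with HLA-A at 321 against 18.2 FPKM (4.07 ± 0.21), PSMB9 at 90.9 against 10.5 FPKM and TAPBP at 148 against 35.7 FPKM. HLA genes share reads with close relatives. In 293T spheres 4 of 12 were higher and 1 lower, and HLA-A was 40.0 against 54.8 FPKM.

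Chaperonin and prefoldin subunits, which fold actin and tubulin, were lower in MCF-7 spheres for 10 of 14 genes and higher for 1, with a median of -1.45 (7 lower, 1 higher and -0.96 after GC centring). CCT5 was 29.9 against 218 FPKM (-2.82 ± 0.19) and CCT6A 8.98 against 82.3 FPKM, while PFDN5 was higher at 889 against 439 FPKM. In 293T spheres none was higher and 2 were lower. Vacuolar ATPase subunits, which acidify lysosomes, had 7 higher and 2 lower of 16 in MCF-7 spheres (median 0.86, and 0.84 after GC centring) and 2 higher and 4 lower in 293T spheres (-0.43). ATP6V0B was 551 against 301 FPKM in MCF-7, which is under 2-fold (0.87, and 0.20 after GC centring), and 69.9 against 304 FPKM in 293T. Among metalloproteinase inhibitors and insulin-like growth factor binding proteins, TIMP2, which overlaps another listed locus, was 30.5 against 0.372 FPKM in MCF-7 spheres (4.52 ± 0.32) and 11.98 against 5.40 FPKM in 293T spheres, and IGFBP6 was 12.5 against 1.65 FPKM in 293T spheres. That group had 4 of 7 measured genes higher and none lower in MCF-7 (median 1.57), and 3 higher and none lower after GC centring (0.69). In 293T 4 were higher and 1 lower of 7 (1.02).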
